A study of Mus musculus with 21 samples.

How the data were processed

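Gene expression was measured by total RNA sequencing of 21 libraries from sorted cells of day 4 mouse embryoid bodies, in 7 groups of 3 taken from the sample labels. The authors deposited raw counts per Ensembl gene, made with featureCounts against mm10 per the labels, without a version, and no normalization had been applied to the counts. Aligner, annotation and strand setting were not stated. The 12 reporter-line libraries came as a table, and the 9 WT and iEtv2 libraries as separate files that also held summary entries for reads outside genes: 3.95 to 5.25% unmapped, 7.34 to 8.75% mapped to several places, 5.04 to 7.91% in no feature and 4.3 to 4.91% ambiguous. Such entries are of the kind STAR writes and not those of featureCounts, so the tool named in the labels is in doubt for these 9 files. These entries were left out of library sizes and tests. Each file held 55487 gene IDs, of which 55227 were named from GENCODE M21 and 260 stayed without a name.

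Tests used R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM, genes were kept by filterByExpr with its defaults, and a quasi-likelihood model with a term per group gave two-sided tests. The 12 reporter-line libraries were fitted together and the 9 others together, because the sets had been counted differently. There were 7 comparisons: the Etv2 reporter in DP and in SP, SP over DP without and with the reporter, the difference between the reporter effects of the gates, SP over DP in WT, and iEtv2 SP over WT SP. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The text names Etv2, Kdr, Pdgfra and T, then the 6 largest increases and 6 largest decreases of a comparison among called genes with a mean of at least 5 CPM and groups that did not overlap, and up to 4 called members of a list with the largest change. Predicted, ribosomal protein, mitochondrial and small RNA genes were left out of the largest changes by symbol. Other names are said to be chosen after their values were seen.

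Gene lists were fixed with the comparisons, the rule for named genes and the main alternatives before the data were examined. There were 22 lists, of which 1 is not reported here. The others were endothelial, arterial and Notch, venous, hematopoietic, primitive erythroid, cardiac progenitor, cardiomyocyte sarcomere, smooth muscle, paraxial mesoderm, primitive streak and nascent mesoderm, lateral plate and extraembryonic mesoderm, mesenchyme and matrix, pluripotency, endoderm, neuroectoderm, cell cycle, Wnt targets, BMP targets, glycolysis and hypoxia, mitochondrial-encoded, and dissociation and stress. Shared members were Sox7 (endothelial, endoderm), Gata6 (cardiac, endoderm), Sp5 (streak, Wnt) and Msx1 and Msx2 (lateral plate, BMP). Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated, and with fry, adjusted over the 22 lists.

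Replicate numbers were taken to pair libraries where every correlation between the numbered libraries, after group means were removed, was over 0.1. This held for the reporter effect in DP (0.175 to 0.342) and in SP (0.143 to 0.268). It did not hold for the gates without the reporter (0.096 to 0.334), with the reporter (0.077 to 0.269) or in WT (0.092 to 0.342), or for iEtv2 over WT (-0.076 to 0.166). In the gates too, libraries of the same number correlated more than those of different numbers in every case, so their pairing stays open. The main tests had no pairing term, also where pairing held. With a replicate block the calls rose to 6214 and 5445 for the reporter in DP and SP. They rose to 2788 and 3370 for the gates without and with it, and to 3242 in WT. Alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, a replicate block, only the compared groups in the fit, removal of mitochondrial and ribosomal RNA genes, a 2-fold minimum, and leaving out each library. Leaving out both reporter-line libraries of high ribosomal RNA share was added after the data were seen.

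The tests were tried on simulated data with 200 changed genes, drawn from those of at least 1 CPM. Between groups, 52.2 to 73.1% of 1.5-fold, 76.1 to 91% of 2-fold and 97 to 100% of 4-fold changes were recovered, and for the interaction 46.3, 73.1 and 98.5%. For 383 genes, 50-base windows taken every 10 bases of the longest transcript were searched in the transcripts of all other genes, and 57 genes had less than 90% and 15 less than 50% of windows unique. Wilson intervals and the floor of 3 counts cover counting error only. Shares, uniqueness and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.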

Results

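RNA was sequenced from mouse embryonic stem cells grown as embryoid bodies, collected on day 4 and sorted on the receptors PDGFRalpha and FLK1, the products of Pdgfra and Kdr. Cells positive for both receptors are called DP here, and cells with FLK1 but without PDGFRalpha are called SP. The first set of libraries came from a reporter line (TGET) that carries a T-GFP and an Etv2-tdTomato reporter. T marks nascent mesoderm, and Etv2 is an ETS transcription factor required for the endothelial and blood lineages. Both gates of this line were split by tdTomato into Etv2-positive and Etv2-negative cells, which gave 4 groups. The second set held DP and SP cells of the wildtype line A2lox.Cre (WT) and SP cells of a line in which doxycycline, given at 2 µg per ml from day 2.5, switches on Etv2 (iEtv2). Each of the 7 groups had 3 libraries, 21 in all. The series title asks how Etv2-positive and Flk1-positive progenitors contribute to endothelial, blood and cardiac lineages.

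Counts assigned to genes came to 25045553, 32777143 and 29157330 in replicates 1 to 3 of the DP Etv2-negative cells and 27503805, 26808438 and 32284183 in the DP Etv2-positive cells. They were 27415801, 30613029 and 28943771 in the SP Etv2-negative and 27787793, 27533753 and 30171521 in the SP Etv2-positive cells. Totals were 26548414, 24094585 and 22406153 in WT DP, 26305285, 26469977 and 24031942 in WT SP and 25602813, 25697189 and 28184904 in iEtv2 SP. At this depth the limit of 3 counts that a count of 0 allows stood for 0.0915 to 0.134 library-scaled counts (CPM), for counting error only. The sets were counted differently, with 12.2 to 14.4% of counts on pseudogenes in the reporter line and 0.549 to 0.636% in the other 9 libraries, so levels are compared within a set only. Ribosomal RNA took 1.40% of the counts (95% Wilson interval 1.39 to 1.40%) in SP Etv2-negative replicate 2 and 1.28% (1.28 to 1.29%) in SP Etv2-positive replicate 3, against at most 0.432% (0.429 to 0.434%) in the other reporter-line libraries. In the second set the share ran from 0.682 to 2.278%, with 7 of the 9 libraries above that 1.28%, and there libraries were left out only 1 at a time. Replicates of a group correlated across genes with Pearson values of 0.990 to 0.994 in the reporter line and 0.987 to 0.994 in the second set, and no library was a copy of another. Nothing in the labels says that replicates were separate cultures, so every p-value measures the spread between these samples, which could be technical. Values after ± are standard errors for log2 fold changes and standard deviations for CPM, with n = 3 libraries per group throughout. These standard errors were derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. They rest on a spread estimated over all libraries of a fit, and are rough for genes near the floor. Adjusted p-values for genes come from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, and those for gene lists from camera, adjusted over the 22 lists of a comparison.

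The sorting genes followed the gates within each set. Etv2 (ENSMUSG00000006311, mm10 chromosome 7, 30633616 to 30635852, minus strand) stood at 20.2 ± 2.61 CPM in DP Etv2-negative cells and 58.4 ± 10.3 in DP Etv2-positive cells, and at 26.6 ± 1.04 and 89 ± 17 CPM in the SP counterparts. Its level was 53.6 ± 4.38 CPM in WT DP, 93.6 ± 22.4 in WT SP and 239 ± 10.2 in iEtv2 SP, a 2.55-fold difference between the last pair (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.88e-05). Pdgfra (ENSMUSG00000029231, mm10 chromosome 5, 75152292 to 75198215) was lower in SP than in DP cells in every background, with log2 fold changes of -2.29 ± 0.20 without and -2.00 ± 0.20 with the Etv2 reporter and -2.99 ± 0.29 in WT. It fell further with induced Etv2, from 40 ± 7.75 to 6.74 ± 3.55 CPM. Kdr (ENSMUSG00000062960, mm10 chromosome 5, 75932827 to 75978458), selected for in every sort, differed little between groups, from 437 ± 96.3 to 604 ± 25.8 CPM in the reporter line and from 858 ± 152 to 892 ± 63.3 in the second set. T (ENSMUSG00000062327, mm10 chromosome 17, 8434423 to 8442496) was lower with the Etv2 reporter in DP cells, 104 ± 29.3 against 37.8 ± 12.5 CPM, and was not called in the other 6 comparisons. It stayed uncalled in 14 of 15 alternative settings for the reporter in SP, 13 of 15 for the gates without and 13 of 15 with the reporter, 17 of 20 for the interaction, 14 of 14 in WT and 12 of 14 with induced Etv2. The labels do not say whether T-GFP was a sort gate.

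**Figure D1:**
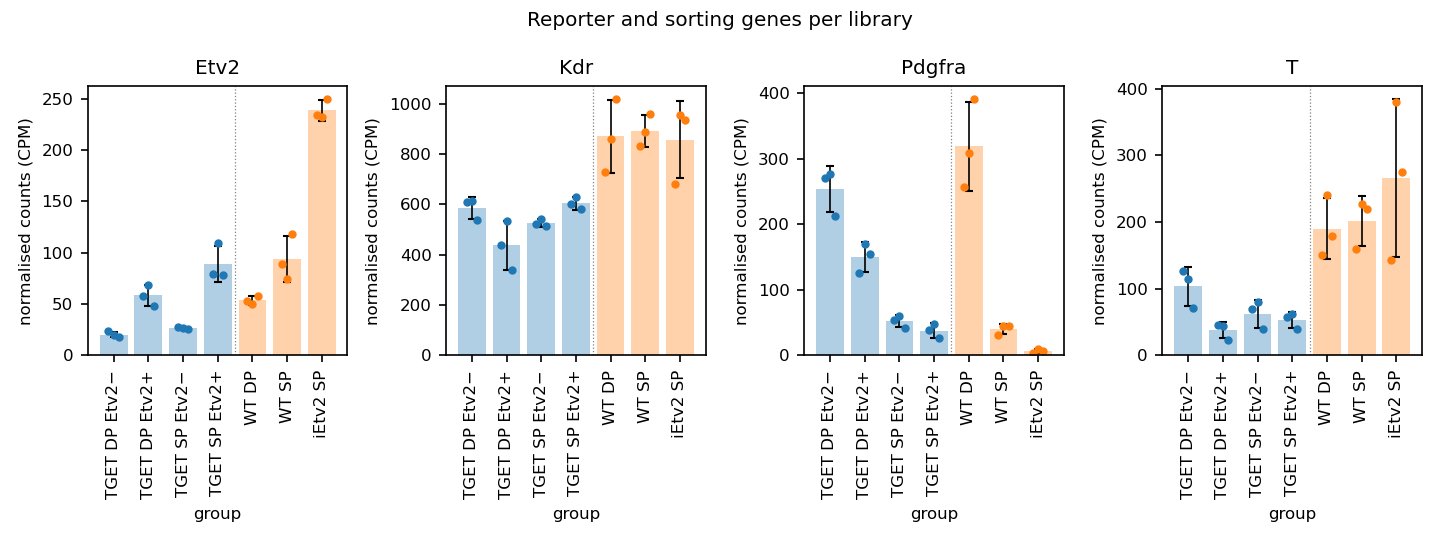
Normalised counts (CPM, linear axes from 0) of Etv2, Kdr, Pdgfra and T in each of the 7 groups, with points for single libraries, bars for group means and error bars for the SD (n = 3). The dotted line parts the reporter line from the WT and iEtv2 libraries, which were counted differently and are not compared across it; Etv2 reached 239 CPM in iEtv2 SP and Pdgfra fell to 6.74 CPM there.

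The first comparison asked which genes went with Etv2 reporter activity among cells that carried PDGFRalpha. DP Etv2-positive cells had higher levels of some blood and endothelial regulators and lower levels of most paraxial mesoderm genes than DP Etv2-negative cells. With an estimated correlation the paraxial call held, and the endothelial and hematopoietic calls were lost (adjusted p = 0.303 for each). The largest increases among genes of at least 5 CPM were in Tal1, a transcription factor that specifies blood and endothelium (4.14 ± 0.46 on the log2 scale, or 17.6-fold), Parm1 (3.26 ± 0.30), the BMP-family ligand Gdf6 (2.97 ± 0.31), the tryptophan-degrading enzyme Tdo2 (2.83 ± 0.45) and both subunits of the nitric oxide receptor guanylate cyclase, Gucy1b1 (2.81 ± 0.40) and Gucy1a1 (2.80 ± 0.52). The largest decreases were in Mesp2, which patterns forming somites (-3.71 ± 0.22), the Notch ligand Dll1 (-3.69 ± 0.25), Rimbp2 (-3.48 ± 0.21), the protocadherins Pcdh8 (-3.42 ± 0.36) and Pcdh19 (-3.37 ± 0.22), and the neurotrophic factor receptor Gfra3 (-3.23 ± 0.17). For these 12 genes the highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p was 0.00131 (Gucy1a1), and by the rule of choice the groups did not overlap, which chance gives in 10% of genes.

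Paraxial mesoderm genes were mostly lower in DP Etv2-positive cells. Of the 14 paraxial mesoderm genes tested, 1 was higher, 10 lower and 3 not called. Paraxial mesoderm genes adjusted over the list alone gave 1 higher and 10 lower (camera adjusted p = 4.95e-15, and adjusted p = 0.0139 with an estimated correlation). Beside Mesp2 and Dll1 they included Dll3 (-2.99 ± 0.31) and the retinoic acid synthesis enzyme Aldh1a2 (-2.92 ± 0.21), while the somite homeobox gene Meox1, named as the exception after its value was seen, was higher (1.28 ± 0.16). Among 21 genes of the primitive streak and nascent mesoderm, 0 were higher, 16 lower and 5 not called, 0 and 17 adjusted over the list alone (camera adjusted p = 2.69e-10, and adjusted p = 0.215 with an estimated correlation). The Nodal antagonist Lefty2 (-3.17 ± 0.50), Wnt8a (-2.89 ± 0.29), the early cardiac mesoderm factor Mesp1 (-2.54 ± 0.27) and Lhx1 (-2.44 ± 0.37) were among the lower ones. Of the 20 pluripotency genes tested, 1 was higher, 9 lower and 10 not called. Pluripotency genes adjusted over the list alone gave 1 higher and 10 lower (camera adjusted p = 9.29e-06, and adjusted p = 0.0634 with an estimated correlation). The lower ones included Fgf4 (-2.44 ± 0.21), Nanog (-2.04 ± 0.26) and Pou5f1 (-2.01 ± 0.23).

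Endothelial and blood genes were higher in part. Of the 27 endothelial genes tested, 13 were higher, 1 lower and 13 not called. Endothelial genes adjusted over the list alone gave 14 higher and 2 lower (camera adjusted p = 1.72e-07, and adjusted p = 0.303 with an estimated correlation). The SoxF factor Sox7 (4.21 ± 0.47) and the angiopoietin receptor Tek (3.19 ± 0.62) were higher. Robo4, named here because it went the other way, was lower (-0.85 ± 0.28). The 18 hematopoietic genes tested held 5 higher, 0 lower and 13 not called. Hematopoietic genes adjusted over the list alone gave 5 higher and 0 lower (camera adjusted p = 0.000354, and adjusted p = 0.303 with an estimated correlation). Runx1, a regulator of blood stem cell emergence (0.91 ± 0.15), and Gata2 (0.93 ± 0.21) were among the blood genes that were higher. Among the 12 arterial and Notch genes tested, 3 were higher, 5 lower and 4 not called. Arterial and Notch genes adjusted over the list alone gave 3 higher and 5 lower (camera adjusted p = 0.433, not called), with Efnb2 higher (0.76 ± 0.11) and Notch1 (-1.12 ± 0.14) and Jag1 (-1.95 ± 0.19) lower. The 5 venous genes tested held 0 higher, 2 lower and 3 not called. Venous genes adjusted over the list alone gave 0 higher and 3 lower, with the list pointing lower (camera adjusted p = 0.0326, and adjusted p = 0.215 with an estimated correlation).

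Muscle genes leaned higher too. Contractile genes that were higher included Tnnc1 (2.70 ± 0.21), the calcium release channel Ryr2 (2.60 ± 0.28), Myl4 (1.80 ± 0.21) and Tnnt2 (1.67 ± 0.23). The 11 cardiomyocyte sarcomere genes tested held 5 higher, 2 lower and 4 not called. Cardiomyocyte sarcomere genes adjusted over the list alone gave 6 higher and 2 lower (camera adjusted p = 0.00132, and adjusted p = 0.164 with an estimated correlation). Of the 11 smooth muscle genes tested, 8 were higher, 0 lower and 3 not called. Smooth muscle genes adjusted over the list alone gave 8 higher and 1 lower (camera adjusted p = 5.46e-06, and adjusted p = 0.155 with an estimated correlation). They included Myl9 (2.42 ± 0.31) and Acta2 (1.36 ± 0.20). Cardiac progenitor genes split, with the heart factors Nkx2-5 (1.71 ± 0.16) and Tbx5 (1.61 ± 0.14) higher and the second heart field gene Isl1 lower (-1.75 ± 0.08). The 21 cardiac progenitor genes tested held 8 higher, 2 lower and 11 not called. Cardiac progenitor genes adjusted over the list alone gave 8 higher and 2 lower (camera adjusted p = 0.284, not called). The collagen gene Col1a1 was higher (2.28 ± 0.34). Of the 18 mesenchyme and matrix genes tested, 9 were higher, 2 lower and 7 not called. Mesenchyme and matrix genes adjusted over the list alone gave 11 higher and 3 lower (camera adjusted p = 0.00673, and adjusted p = 0.409 with an estimated correlation). Genes of glycolysis and hypoxia, such as the kinase Pdk1 (-1.87 ± 0.46), were mostly lower. The 19 glycolysis and hypoxia genes tested held 1 higher, 10 lower and 8 not called. Glycolysis and hypoxia genes adjusted over the list alone gave 1 higher and 12 lower (camera adjusted p = 0.00174, and adjusted p = 0.556 with an estimated correlation).

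Of 17690 genes tested in the reporter line, 5435 differed between DP Etv2-positive and Etv2-negative cells by edgeR quasi-likelihood at a Benjamini-Hochberg adjusted p below 0.05, with 2827 higher and 2608 lower, and 1276 of them (586 higher, 690 lower) changed at least 2-fold. Upper-quartile normalization turned the balance of directions, with 2495 higher and 2931 lower. Kdr changed by -0.42 ± 0.12 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0158), a call lost without DP Etv2-negative replicate 2 (adjusted p = 0.0546) and with only the compared groups in the fit (0.0567).

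The same question was asked in SP cells, which lacked PDGFRalpha. Here endothelial and blood genes made up the clearest group, and Etv2-positive cells stood higher in most of them, though both list calls were lost with an estimated correlation (adjusted p = 0.0711 for each). The largest increases were in Slc32a1, a vesicular transporter of inhibitory transmitters of which 76.4% of 50-base windows occur in no other gene (3.6 ± 0.59), Sox7 (3.33 ± 0.31, or 10.1-fold), Tal1 (3.16 ± 0.32), the blood corepressor Cbfa2t3 (3.06 ± 0.30), the secreted protein gene Scube2 (3.02 ± 0.26) and Tek (2.82 ± 0.45). The largest decreases were in the integrin Itga8 (-2.83 ± 0.22), Trim67 (-2.77 ± 0.29), Mesp1 (-2.62 ± 0.29), the cytochrome P450 Cyp2s1 (-2.54 ± 0.27), the collagen Col9a1 (-2.48 ± 0.26) and the Notch ligand Dll3 (-2.33 ± 0.35). Slc32a1 had the highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of these 12, 0.00102.

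Of the 27 endothelial genes tested, 23 were higher, 0 lower and 4 not called. Counts for endothelial genes adjusted over the list alone were 24 higher and 0 lower (camera adjusted p = 2.3e-25, and adjusted p = 0.0711 with an estimated correlation). Icam2 (3.41 ± 0.63) and Vwf (3.09 ± 0.44), which encode endothelial adhesion proteins, were among the 4 largest changes with Sox7 and Tal1. Of the 18 hematopoietic genes tested, 16 were higher, 1 lower and 1 not called. Counts for hematopoietic genes adjusted over the list alone were 16 higher and 1 lower (camera adjusted p = 9.09e-16, and adjusted p = 0.0711 with an estimated correlation), with increases in Lyl1 (2.92 ± 0.40) and Gfi1 (2.78 ± 0.36). Some primitive erythroid genes were higher as well, among them the heme synthesis enzyme Alas2 (3.07 ± 0.49). The 6 primitive erythroid genes tested held 4 higher, 0 lower and 2 not called. Primitive erythroid genes adjusted over the list alone gave 4 higher and 0 lower (camera adjusted p = 0.00561, and adjusted p = 0.211 with an estimated correlation). The embryonic globin Hbb-bh1 stood at 0.268 ± 0.257 CPM in Etv2-negative and 3.38 ± 2.89 CPM in Etv2-positive SP cells. Gja4, an arterial connexin, was higher (3 ± 0.52), while the venous list of 5 genes had no called member (camera adjusted p = 0.9).

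Mesoderm genes leaned lower. Of the 14 paraxial mesoderm genes tested, 2 were higher, 7 lower and 5 not called. Counts for paraxial mesoderm genes adjusted over the list alone were 2 higher and 7 lower (camera adjusted p = 3.31e-05, and adjusted p = 0.147 with an estimated correlation). The lower ones included Dll1 (-3.21 ± 0.31), the presomitic factor Msgn1 (-2.94 ± 0.35) and Mesp2 (-2.77 ± 0.28). Streak genes such as Fgf8 (-1.85 ± 0.35) and Wnt8a (-1.79 ± 0.34) were lower. The 21 primitive streak and nascent mesoderm genes tested held 1 higher, 9 lower and 11 not called. Primitive streak and nascent mesoderm genes adjusted over the list alone gave 1 higher and 12 lower (camera adjusted p = 1.3e-05, and adjusted p = 0.331 with an estimated correlation). Of the 20 pluripotency genes tested, 0 were higher, 11 lower and 9 not called. Counts for pluripotency genes adjusted over the list alone were 1 higher and 14 lower (camera adjusted p = 1.3e-05, and adjusted p = 0.0711 with an estimated correlation), with decreases in Prdm14 (-2.67 ± 0.32) and Nanog (-1.85 ± 0.27). In the cardiac progenitor list, 3 genes were higher, 5 lower and 13 not called, 4 and 6 adjusted over the list alone (camera adjusted p = 0.9, not called). Nkx2-5 (2.42 ± 0.16) and Tbx5 (1.66 ± 0.14) were again higher, and Isl1 (-1.91 ± 0.09) and Mef2c (-2.27 ± 0.44) lower. Some glycolysis and hypoxia genes were lower. The 19 glycolysis and hypoxia genes tested held 0 higher, 11 lower and 8 not called. Glycolysis and hypoxia genes adjusted over the list alone gave 0 higher and 12 lower (camera adjusted p = 0.000745, and adjusted p = 0.6 with an estimated correlation). Mitotic kinase genes such as Aurka (0.46 ± 0.05) and Plk1 (0.38 ± 0.05) were slightly higher. The 24 cell cycle genes tested held 9 higher, 1 lower and 14 not called. Cell cycle genes adjusted over the list alone gave 10 higher and 1 lower (camera adjusted p = 0.00215, and adjusted p = 0.211 with an estimated correlation).

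Most transcripts of the mitochondrial genome had higher values in SP Etv2-positive cells. Unique 50-base windows made up 0% of mt-Co2, mt-Co3 and mt-Nd4l, 1.6% of mt-Atp6, 3.3% of mt-Nd3, 37.6% of mt-Nd4 and 48.7% of mt-Co1. They made up at least 91.9% of the other members. Values of the genes with few unique windows are uncertain in every comparison. The 13 mitochondrial-encoded genes tested held 10 higher, 0 lower and 3 not called. Mitochondrial-encoded genes adjusted over the list alone gave 11 higher and 0 lower (camera adjusted p = 3.44e-06, and adjusted p = 0.235 with an estimated correlation). Their share of all counts was 2.94 to 3.08% in the 3 SP Etv2-positive libraries and 2.15 to 2.60% in the other 9 libraries of the line, and it moved with the endothelial and blood genes.

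In all, 4504 genes differed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), 2314 higher and 2190 lower, and 905 of them (322 higher, 583 lower) by at least 2-fold. The balance of directions depended on scaling, with 1800 higher and 2653 lower under upper-quartile normalization. Leaving out both libraries of high ribosomal RNA share, a choice made after the data were seen, gave 2459.

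Among cells without Etv2 reporter signal, SP cells were set against DP cells to ask what went with the absence of PDGFRalpha. Blood and endothelial regulators were in part higher in SP cells, and paraxial and streak genes in part lower. With an estimated correlation the paraxial call held, and the endothelial, hematopoietic and streak calls were lost (adjusted p = 0.188, 0.0903 and 0.196). The largest increases were in Tal1 (4.09 ± 0.46), Parm1 (2.35 ± 0.30), Exoc3l (2.19 ± 0.31), the calcium-regulated factor Nfatc2 (2.17 ± 0.27), the connexin Gjb2 (2.15 ± 0.26) and the growth factor Pdgfb, a ligand of PDGF receptors (2.12 ± 0.16, or 4.35-fold). The largest decreases were in Lefty2 (-3.56 ± 0.52), Wnt2b (-2.72 ± 0.36), Rimbp2 (-2.70 ± 0.20), the somite and vessel factor Foxc2 (-2.55 ± 0.21), Pcdh19 (-2.52 ± 0.20) and Mesp2 (-2.47 ± 0.19), with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of at most 0.00116 (Lefty2) over all 12.

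Of the 27 endothelial genes tested, 12 were higher, 1 lower and 14 not called. Endothelial genes adjusted over the list alone gave 15 higher and 1 lower (camera adjusted p = 2.36e-14, and adjusted p = 0.188 with an estimated correlation), with Sox7 higher (3.61 ± 0.49). Of the 18 hematopoietic genes tested, 11 were higher, 0 lower and 7 not called. Hematopoietic genes adjusted over the list alone gave 13 higher and 0 lower (camera adjusted p = 2.27e-11, and adjusted p = 0.0903 with an estimated correlation). The mitochondrial-encoded list, a sign of RNA quality, moved the same way, with 1 of 13 genes higher, 0 lower and 12 not called, and as many adjusted over the list alone (camera adjusted p = 0.0394, and adjusted p = 0.489 with an estimated correlation). Of the 14 paraxial mesoderm genes tested, 0 were higher, 8 lower and 6 not called. Paraxial mesoderm genes adjusted over the list alone gave 0 higher and 10 lower (camera adjusted p = 6.85e-22, and adjusted p = 0.00375 with an estimated correlation), and Dll1 (-2.27 ± 0.22) and the Notch modifier Lfng (-2.23 ± 0.27) were among the lower genes. Lhx1 (-2.04 ± 0.36) and Gsc (-1.84 ± 0.37) of the streak were lower beside Lefty2. The 21 primitive streak and nascent mesoderm genes tested held 1 higher, 11 lower and 9 not called. Primitive streak and nascent mesoderm genes adjusted over the list alone gave 1 higher and 14 lower (camera adjusted p = 1.09e-10, and adjusted p = 0.196 with an estimated correlation). Lateral plate genes leaned higher, among them Tbx2 (0.85 ± 0.15) and Bmp4 (0.81 ± 0.16). The 16 lateral plate and extraembryonic mesoderm genes tested held 4 higher, 0 lower and 12 not called. Lateral plate and extraembryonic mesoderm genes adjusted over the list alone gave 4 higher and 0 lower (camera adjusted p = 0.000412, and adjusted p = 0.33 with an estimated correlation). The anterior neural genes Otx1 (-2.19 ± 0.33) and Otx2 (-2.06 ± 0.38) were lower. The 9 neuroectoderm genes tested held 1 higher, 4 lower and 4 not called. Neuroectoderm genes adjusted over the list alone gave 2 higher and 5 lower (camera adjusted p = 0.0191, and adjusted p = 0.244 with an estimated correlation). Of the 17 endoderm genes tested, 4 were higher, 1 lower and 12 not called. Endoderm genes adjusted over the list alone gave 5 higher and 2 lower (camera adjusted p = 0.0394, and adjusted p = 0.393 with an estimated correlation), but Sox7 is also an endothelial gene. Mitotic genes such as Cdc20 (-0.48 ± 0.07) and Aurkb (-0.37 ± 0.06) were slightly lower. The 24 cell cycle genes tested held 0 higher, 12 lower and 12 not called. Cell cycle genes adjusted over the list alone gave 0 higher and 15 lower (camera adjusted p = 7.52e-10, and adjusted p = 0.0293 with an estimated correlation). No glycolysis or hypoxia gene of the 19 tested was called (camera adjusted p = 0.671), and no glycolysis or hypoxia gene was called when adjusted over the list alone.

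Here 1936 genes differed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), 1079 higher and 857 lower in SP, with 494 of at least 2-fold. This count rested on single libraries, falling to 787 without DP Etv2-negative replicate 1, 815 without its replicate 2, 1049 without SP Etv2-negative replicate 1 and 1092 without its replicate 3.

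Within Etv2-positive cells, SP and DP cells were compared to ask how cells without PDGFRalpha differed from those with it. Most blood and endothelial genes were higher in SP cells. Some mesenchyme and matrix genes were lower, a list call lost with an estimated correlation (adjusted p = 0.487). The largest increases were in the blood transcription factors Ikzf1 (4.59 ± 0.57, or 24.1-fold) and Myb (3.55 ± 0.52), in Slc32a1 (3.83 ± 0.60), Cdh5 (3.49 ± 0.41), the kinase Wnk4 (3.45 ± 0.40) and the amino acid transporter Slc7a8 (3.43 ± 0.22). The largest decreases were in the mesenchymal factor Snai2 (-2.10 ± 0.54), Lefty2 (-2.03 ± 0.62), Pdgfra, the hypoxia-inducible factor gene Epas1 (-1.60 ± 0.34), Mesp1 (-1.56 ± 0.28) and Dll3 (-1.53 ± 0.35). By edgeR quasi-likelihood the Benjamini-Hochberg adjusted p was 0.0236 for Snai2, 0.0449 for Lefty2 and 0.014 for Dll3, and at most 0.00893 (Epas1) for the other 9. Snai2 passed the threshold only with DP Etv2-positive replicate 3 (0.0868 without it) and all of SP Etv2-positive replicates 1 to 3 (0.0823, 0.0728 and 0.0572), and Dll3 only with SP Etv2-positive replicate 3 (0.0583). Without both libraries of high ribosomal RNA share, the adjusted p was 0.0687 for Snai2, 0.144 for Lefty2 and 0.0555 for Dll3. Lefty2 lost its call without DP Etv2-positive replicate 1 or 2 (0.139 and 0.0991) and without any 1 of SP Etv2-positive replicates 1 to 3 (0.112, 0.0698 and 0.146).

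Of the 27 endothelial genes tested, 22 were higher, 0 lower and 5 not called. Endothelial genes adjusted over the list alone gave 24 higher and 0 lower (camera adjusted p = 7.71e-36, and adjusted p = 0.0427 with an estimated correlation). Erg (3.45 ± 0.44), Esam (3.40 ± 0.45) and the receptor Tie1 (3.27 ± 0.63) followed Cdh5 in size. Levels in DP were near the count floor for Erg (0.335 ± 0.0669 CPM) and Tie1 (0.281 ± 0.134 CPM). Of the 18 hematopoietic genes tested, 16 were higher, 1 lower and 1 not called. Hematopoietic genes adjusted over the list alone gave 16 higher and 1 lower (camera adjusted p = 9.52e-28, and adjusted p = 0.0259 with an estimated correlation), among them the repressor Gfi1b (5.19 ± 0.73) and the erythroid factor Gata1 (4.01 ± 0.57). Gata1 stood at 0.217 ± 0.0539 CPM in DP, also near the floor, and at 3.59 ± 2.39 CPM in SP. The adaptor gene Fyb, named because it went the other way, was lower (-1.46 ± 0.19). Alas2 (3.33 ± 0.51) and the erythroid factor Klf1 (4.01 ± 0.72) were higher. The 6 primitive erythroid genes tested held 3 higher, 0 lower and 3 not called. Primitive erythroid genes adjusted over the list alone gave 4 higher and 0 lower (camera adjusted p = 9.87e-05, and adjusted p = 0.0959 with an estimated correlation). Mesenchyme and matrix genes, Snai2 among them, leaned lower. The 18 mesenchyme and matrix genes tested held 1 higher, 7 lower and 10 not called. Mesenchyme and matrix genes adjusted over the list alone gave 1 higher and 8 lower (camera adjusted p = 0.0289, and adjusted p = 0.487 with an estimated correlation). Venous genes leaned higher through the semaphorin receptor Nrp2 (0.63 ± 0.13). The 5 venous genes tested held 2 higher, 0 lower and 3 not called. Venous genes adjusted over the list alone gave 3 higher and 0 lower (camera adjusted p = 0.0293, and adjusted p = 0.193 with an estimated correlation). No smooth muscle gene of 11 was called, nor adjusted over the list alone (camera adjusted p = 0.656). The mitochondrial-encoded list moved with the blood and endothelial genes. The 13 mitochondrial-encoded genes tested held 10 higher, 0 lower and 3 not called. Mitochondrial-encoded genes adjusted over the list alone gave 12 higher and 0 lower (camera adjusted p = 9.13e-10, and adjusted p = 0.169 with an estimated correlation).

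Etv2 itself was higher in SP by 0.61 ± 0.14 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0131), a call lost without SP Etv2-positive replicate 2 (0.054). Kdr was higher by 0.46 ± 0.12 (adjusted p = 0.0215), a call lost without DP Etv2-positive replicate 1 (0.0542), without SP Etv2-positive replicate 1 (0.0569) or 2 (0.07), with only the compared groups in the fit (0.0687), and without both libraries of high ribosomal RNA share (0.0598). In total 2456 genes differed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), 1229 higher and 1227 lower, with 431 of at least 2-fold. The count fell to 1359, 1593 and 1342 without SP Etv2-positive replicate 1, 2 or 3, to 1324 with only the compared groups in the fit, and to 1106 without both libraries of high ribosomal RNA share.

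Whether the Etv2 effect differed between the gates was tested directly, as the effect in SP minus the effect in DP. Some contractile, lateral plate and BMP target genes had a lower reporter effect in SP than in DP, though these list calls were lost with an estimated correlation (adjusted p = 0.12, 0.167 and 0.124). Notch1, Foxc2 and Aplnr were lower with the reporter in DP and had no called decrease in SP. Ripor3 had the lowest adjusted p of the 12 genes named here (-2.48 ± 0.34), with an increase of 2.5 in DP and 0.03 in SP. The tryptophan-degrading enzyme Tdo2 (-2.77 ± 0.62) and the guanylate cyclase subunit Gucy1b1 (-2.34 ± 0.55) followed the same course, as did Extl1 (-2.43 ± 0.39). Spin2c (-2.54 ± 0.38) was higher with the reporter in DP, by 1.87, and not called in SP (-0.68). Prrt4 (-2.65 ± 0.46) was not called in DP (0.85) and lower in SP (-1.8). In the other direction were the membrane repair gene Dysf (2.37 ± 0.38) and Inka1 (2.21 ± 0.36), with values of -1.14 and -0.59 in DP, the latter not called, and 1.23 and 1.62 in SP. The adrenergic receptor gene Adra2a (2.34 ± 0.46) and Wnt2b (2.16 ± 0.51) were lower with the reporter in DP only by call, and Scube2 (1.87 ± 0.41) and the blood and endothelial homeobox gene Hhex (1.73 ± 0.37) had higher values in SP (3.02 and 2.16) than in DP (1.15 and 0.43, the latter not called).

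Of the 12 BMP target genes tested, 0 were higher, 6 lower and 6 not called. BMP target genes adjusted over the list alone gave 1 higher and 8 lower (camera adjusted p = 2.38e-06, and adjusted p = 0.124 with an estimated correlation). Of the 16 lateral plate and extraembryonic mesoderm genes tested, 0 were higher, 5 lower and 11 not called. Lateral plate and extraembryonic mesoderm genes adjusted over the list alone gave 0 higher and 7 lower (camera adjusted p = 9.84e-07, and adjusted p = 0.167 with an estimated correlation), and the Msx genes Msx1 and Msx2 belong to both lists. Of the 11 cardiomyocyte sarcomere genes tested, 0 were higher, 4 lower and 7 not called. Cardiomyocyte sarcomere genes adjusted over the list alone gave 1 higher and 5 lower (camera adjusted p = 0.000461, and adjusted p = 0.12 with an estimated correlation), with Tnnc1 at -1.87 ± 0.29. Among paraxial genes Foxc2 had a positive difference (3.09 ± 0.31). The 14 paraxial mesoderm genes tested held 3 higher, 0 lower and 11 not called. Paraxial mesoderm genes adjusted over the list alone gave 5 higher and 0 lower (camera adjusted p = 1.12e-06, and adjusted p = 0.11 with an estimated correlation). Notch1 (1.51 ± 0.19, 86.3% unique 50-base windows) and the apelin receptor Aplnr (1.08 ± 0.14) had positive differences. Of the 12 arterial and Notch genes tested, 1 was higher, 1 lower and 10 not called. Arterial and Notch genes adjusted over the list alone gave 3 higher and 2 lower (camera adjusted p = 0.0439, and adjusted p = 0.233 with an estimated correlation). The lower one was the netrin receptor gene Unc5b (-0.59 ± 0.14), a call lost without any 1 library except DP Etv2-negative replicate 3 and DP Etv2-positive replicate 1 (adjusted p of 0.0516 to 0.12), and without both libraries of high ribosomal RNA share (0.124). Of the 5 venous genes tested, 1 was higher, 0 lower and 4 not called. Venous genes adjusted over the list alone gave 2 higher and 0 lower (camera adjusted p = 0.00232, and adjusted p = 0.12 with an estimated correlation). Of the 18 hematopoietic genes tested, 3 were higher, 1 lower and 14 not called. Hematopoietic genes adjusted over the list alone gave 4 higher and 1 lower (camera adjusted p = 0.00133, and adjusted p = 0.288 with an estimated correlation). Of the 27 endothelial genes tested, 3 were higher, 0 lower and 24 not called. Endothelial genes adjusted over the list alone gave 7 higher and 0 lower (camera adjusted p = 0.00139, and adjusted p = 0.405 with an estimated correlation). The mitochondrial-encoded list, a sign of RNA quality, moved the same way, with 0 of 13 genes called (camera adjusted p = 0.000461, and adjusted p = 0.324 with an estimated correlation). Of the 24 cell cycle genes tested, 5 were higher, 0 lower and 19 not called. Cell cycle genes adjusted over the list alone gave 12 higher and 0 lower (camera adjusted p = 4.41e-07, and adjusted p = 0.11 with an estimated correlation).

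The test called 702 genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), 269 with a higher and 433 with a lower value in SP, 269 of the 702 with a difference of at least 2-fold. Of the 433, 263 were higher with the reporter in DP and not called in SP, and of the 269, 132 were lower in DP and not called in SP. These calls sat close to the threshold, and a replicate block gave 1537. The count fell to 114 and 50 without DP Etv2-negative replicates 1 and 2, to 211 without DP Etv2-positive replicate 3, to 143, 367 and 162 without SP Etv2-negative replicates 1, 2 and 3, and to 188 and 190 without SP Etv2-positive replicates 2 and 3, and it rose to 1268 without DP Etv2-negative replicate 3. Of the 12 genes named first, which had an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0106 to 0.0376, Inka1, Spin2c and Ripor3 kept their calls in every setting tried. The other 9 lost theirs without DP Etv2-negative replicate 2 (adjusted p up to 0.107), 6 each without DP Etv2-positive replicate 3 or SP Etv2-negative replicate 1 or 3, 5 without DP Etv2-negative replicate 1, 4 each without SP Etv2-positive replicate 2 or 3, 3 without SP Etv2-positive replicate 1, and 1 each without DP Etv2-positive replicate 1 or SP Etv2-negative replicate 2. Without both libraries of high ribosomal RNA share 119 genes were called.

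**Figure D2:**
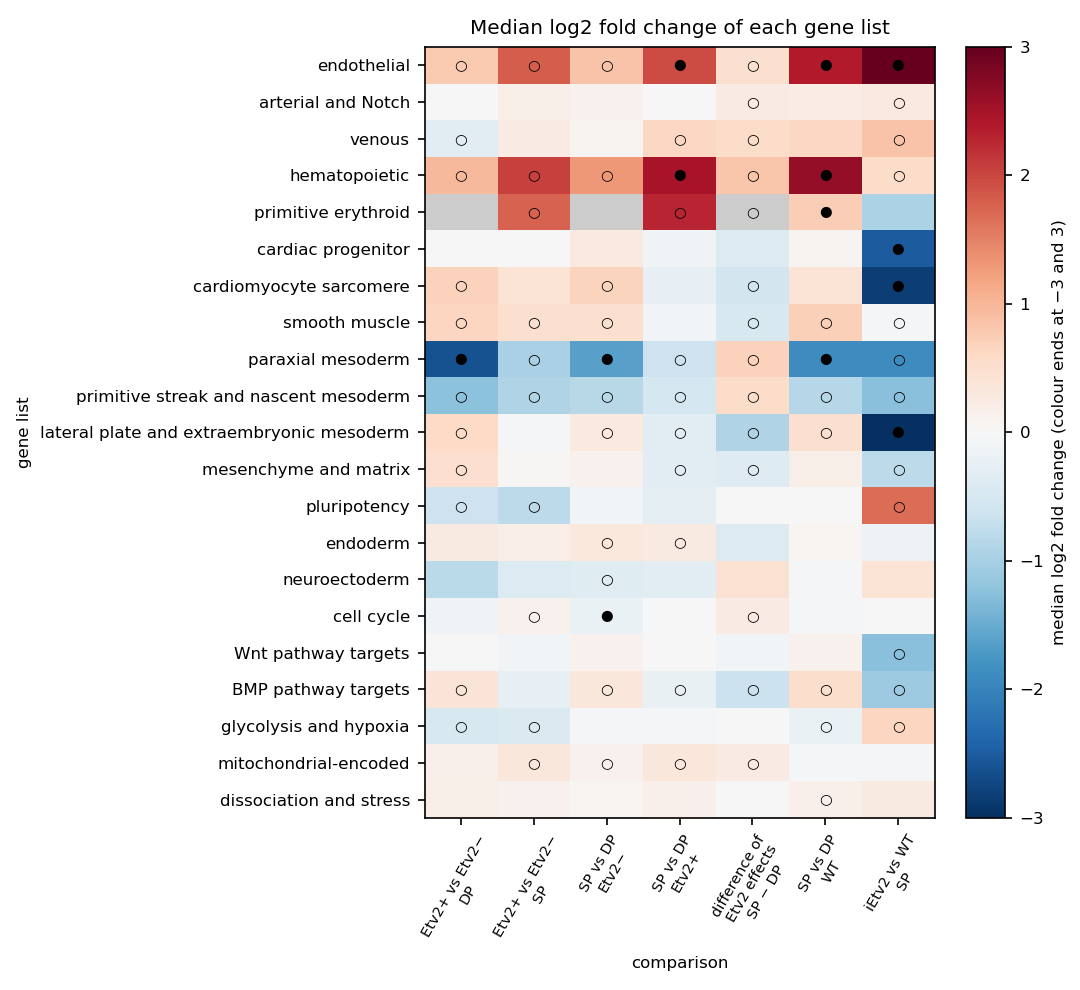
Median log2 fold change of the tested members of 21 gene lists (rows) in 7 comparisons (columns), on a colour scale that ends at -3 and 3. Circles mark lists called by camera at a preset correlation of 0.01, filled where the call held with an estimated correlation (13 of 84). Grey cells hold a member with no count in 1 of the groups, and their median was left out of the drawing.

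In the wildtype line the SP and DP gates were compared with no Etv2 reporter in the sort. Most endothelial and blood genes were higher in SP, and genes of the paraxial mesoderm were in part lower. Some streak genes were lower too, a list call lost with an estimated correlation (adjusted p = 0.414). Slc32a1 (4.03 ± 0.41), the hyaluronan link protein gene Hapln1 (3.96 ± 0.36), Sox7 (3.87 ± 0.18), Sox18 (3.70 ± 0.31), Tek (3.64 ± 0.29) and Tal1 (3.51 ± 0.15, or 11.4-fold) showed the largest increases in SP. Rimbp2 (-3.86 ± 0.31), Pcdh19 (-3.27 ± 0.23), Pcdh8 (-3.14 ± 0.36), Lefty2 (-3.09 ± 0.36), Pdgfra and Mesp2 (-2.89 ± 0.28) showed the largest decreases. Lefty2 had the highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of the 12, 0.000312.

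Of the 30 endothelial genes tested, 27 were higher, 0 lower and 3 not called. Counts for endothelial genes adjusted over the list alone were 27 higher and 0 lower (camera adjusted p = 1.52e-83, and adjusted p = 0.0183 with an estimated correlation). Of the 19 hematopoietic genes tested, 19 were higher, 0 lower and 0 not called. Counts for hematopoietic genes adjusted over the list alone were 19 higher and 0 lower (camera adjusted p = 4.34e-43, and adjusted p = 0.0225 with an estimated correlation). They included Lyl1 (4.05 ± 0.38) and Cbfa2t3 (3.46 ± 0.23). Alas2 was higher (1.5 ± 0.28). The 5 primitive erythroid genes tested held 3 higher, 0 lower and 2 not called. Primitive erythroid genes adjusted over the list alone gave 3 higher and 0 lower (camera adjusted p = 0.000536, and adjusted p = 0.0453 with an estimated correlation). The Notch ligand Dll4 (2.62 ± 0.35) and Gja4 (3.29 ± 0.30), both arterial, were higher and the chemokine receptor Cxcr4 lower (-1.43 ± 0.16). The 14 arterial and Notch genes tested held 6 higher, 3 lower and 5 not called. Arterial and Notch genes adjusted over the list alone gave 6 higher and 4 lower (camera adjusted p = 0.0743, not called). Of the 15 paraxial mesoderm genes tested, 0 were higher, 9 lower and 6 not called. Counts for paraxial mesoderm genes adjusted over the list alone were 0 higher and 9 lower (camera adjusted p = 9.21e-13, and adjusted p = 0.0328 with an estimated correlation). Dll1 (-2.87 ± 0.19) and Foxc1 (-2.66 ± 0.24) followed Mesp2 in size. Streak genes such as Lhx1 (-2.67 ± 0.27) and Snai1 (-1.60 ± 0.21) were lower. The 21 primitive streak and nascent mesoderm genes tested held 1 higher, 8 lower and 12 not called. Primitive streak and nascent mesoderm genes adjusted over the list alone gave 1 higher and 11 lower (camera adjusted p = 9.7e-05, and adjusted p = 0.414 with an estimated correlation). Of the 12 BMP target genes tested, 7 were higher, 0 lower and 5 not called. Counts for BMP target genes adjusted over the list alone were 7 higher and 0 lower (camera adjusted p = 0.00208, and adjusted p = 0.233 with an estimated correlation). They included the feedback inhibitor Smad6 (1.02 ± 0.12).

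Wnt target genes split, with Lgr5 higher (2.22 ± 0.18) and Lef1 lower (-0.97 ± 0.13). The 11 Wnt target genes tested held 3 higher, 2 lower and 6 not called. Wnt target genes adjusted over the list alone gave 4 higher and 2 lower (camera adjusted p = 0.385, not called). The pluripotency list was not called (camera adjusted p = 0.454), and its median (0.01) and mean (0.03) were above 0 while the test pointed lower. The stress gene Atf3 was higher in SP (2.24 ± 0.18). The 17 dissociation and stress genes tested held 4 higher, 0 lower and 13 not called. Dissociation and stress genes adjusted over the list alone gave 4 higher and 0 lower (camera adjusted p = 0.0219, and adjusted p = 0.233 with an estimated correlation). Of 16288 genes tested in this set, 2580 differed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), 1479 higher and 1101 lower, with 888 of at least 2-fold. Without WT DP replicate 3 the count was 1525, and without WT SP replicate 1 it was 1509.

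SP cells with induced Etv2 were compared with WT SP cells, which came from another cell line and for which the labels give no doxycycline, so these effects cannot be separated from that of Etv2. Endothelial genes were far higher in iEtv2 SP cells, and most heart and lateral plate mesoderm genes far lower. Most pluripotency genes were higher, a list call lost with an estimated correlation (adjusted p = 0.346). The largest increases were in Igf1, an insulin-like growth factor (5.89 ± 0.24, or 59.1-fold), the incretin receptor Glp1r (5.88 ± 0.19), the calcium-binding S100a16 (5.99 ± 0.32), the scavenger receptor Stab1 (5.85 ± 0.38) and a pair of genes close to the count floor in WT SP. Of that pair, C1ql2 stood at 0.159 ± 0.0755 CPM in WT SP and 11.6 ± 5.2 in iEtv2 SP, and the placental homeobox gene Esx1 at 0.157 to 0.304 and 20.7 to 48.9 CPM. The largest decreases were in Foxf1, a lateral plate transcription factor (-6.49 ± 0.33), the atrial myosin light chain Myl7 (-6.08 ± 0.35), Tbx2 (-5.93 ± 0.27), the heart factor Hand2 (-5.69 ± 0.41), Tlx2 (-5.62 ± 0.41) and Hoxb1 (-5.60 ± 0.32). Levels in iEtv2 SP were near the count floor for Myl7 (0.292 ± 0.0953 CPM), Tlx2 (0.236 ± 0.201) and Hoxb1 (0.41 ± 0.374), so these sizes are rough. Over these 12 genes the edgeR quasi-likelihood, Benjamini-Hochberg adjusted p was at most 2.6e-06 (C1ql2).

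Of the 30 endothelial genes tested, 30 were higher, 0 lower and 0 not called. Endothelial genes adjusted over the list alone gave 30 higher and 0 lower (camera adjusted p = 1.85e-44, and adjusted p = 0.0264 with an estimated correlation). The tight junction gene Cldn5 (5.80 ± 0.21), Tie1 (5.46 ± 0.26) and Cd34 (5.26 ± 0.31) were among the largest changes. Arterial genes such as Gja4 (3.87 ± 0.19) and Notch4 (3.41 ± 0.28) were higher. The 14 arterial and Notch genes tested held 7 higher, 4 lower and 3 not called. Arterial and Notch genes adjusted over the list alone gave 7 higher and 5 lower (camera adjusted p = 0.0299, and adjusted p = 0.139 with an estimated correlation). The venous factor Nr2f2 was higher (4.73 ± 0.41) and Aplnr lower (-1.22 ± 0.22). The 5 venous genes tested held 3 higher, 1 lower and 1 not called. Venous genes adjusted over the list alone gave 3 higher and 1 lower (camera adjusted p = 0.0212, and adjusted p = 0.235 with an estimated correlation). Blood genes split: the leukocyte genes Laptm5 (3.05 ± 0.25), Lcp1 (2.69 ± 0.22) and Coro1a (2.50 ± 0.20) were higher, and Gata1 (-1.94 ± 0.50) and Runx1 (-1.91 ± 0.12), named after their values were seen, lower. Of the 19 hematopoietic genes tested, 8 were higher, 4 lower and 7 not called. Hematopoietic genes adjusted over the list alone gave 8 higher and 4 lower (camera adjusted p = 0.0239, and adjusted p = 0.466 with an estimated correlation). The embryonic globin Hbb-bh1 was lower (-3.57 ± 0.81), from scattered levels of 2.36 ± 2.36 CPM in WT SP to 0.197 ± 0.03 in iEtv2 SP, near the count floor. The 5 primitive erythroid genes tested held 1 higher, 4 lower and 0 not called. Primitive erythroid genes adjusted over the list alone gave 1 higher and 4 lower (camera adjusted p = 0.243, not called).

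Of the 20 cardiac progenitor genes tested, 1 was higher, 15 lower and 4 not called. Cardiac progenitor genes adjusted over the list alone gave 2 higher and 15 lower (camera adjusted p = 1.6e-14, and adjusted p = 0.0264 with an estimated correlation), with Hand1 (-4.62 ± 0.36), Tbx20 (-4.58 ± 0.12) and Wnt2 (-4.05 ± 0.22) lower. Mef2c, also active in endothelium and named as an exception after its value was seen, was higher (2.19 ± 0.29). Of the 12 cardiomyocyte sarcomere genes tested, 0 were higher, 9 lower and 3 not called. Cardiomyocyte sarcomere genes adjusted over the list alone gave 0 higher and 9 lower (camera adjusted p = 1.63e-07, and adjusted p = 0.0286 with an estimated correlation). Myl4 (-5.07 ± 0.28), Tnni1 (-4.55 ± 0.69) and Actc1 (-3.90 ± 0.28) followed Myl7 in size. In iEtv2 SP, Myl4 (0.198 ± 0.0669 CPM) and Tnni1 (0.172 ± 0.156 CPM) stood near the count floor, so the sizes of their decreases are rough. Of the 14 lateral plate and extraembryonic mesoderm genes tested, 1 was higher, 13 lower and 0 not called. Lateral plate and extraembryonic mesoderm genes adjusted over the list alone gave 1 higher and 13 lower (camera adjusted p = 7.14e-19, and adjusted p = 0.0264 with an estimated correlation), with Bmp5 lower (-5.25 ± 0.23, 51.6% unique 50-base windows). Of the BMP targets, Msx2 (-4.91 ± 0.18) and the BMP antagonist Nog (-3.45 ± 0.28) were lower. The 12 BMP target genes tested held 1 higher, 9 lower and 2 not called. BMP target genes adjusted over the list alone gave 1 higher and 9 lower (camera adjusted p = 8.59e-08, and adjusted p = 0.0713 with an estimated correlation). Of the 11 Wnt target genes tested, 1 was higher, 9 lower and 1 not called. Wnt target genes adjusted over the list alone gave 1 higher and 9 lower (camera adjusted p = 4.23e-06, and adjusted p = 0.139 with an estimated correlation), with decreases in Nkd1 (-2.19 ± 0.13) and Lef1 (-2.08 ± 0.14). Smooth muscle genes included Cnn1 (-2.95 ± 0.19). The 9 smooth muscle genes tested held 0 higher, 4 lower and 5 not called. Smooth muscle genes adjusted over the list alone gave 0 higher and 4 lower (camera adjusted p = 0.0196, and adjusted p = 0.235 with an estimated correlation).

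Of the 21 pluripotency genes tested, 16 were higher, 1 lower and 4 not called. Pluripotency genes adjusted over the list alone gave 17 higher and 2 lower (camera adjusted p = 0.000101, and adjusted p = 0.346 with an estimated correlation). Utf1 (4.03 ± 0.42), Pou5f1 (2.57 ± 0.16) and Klf2 (2.29 ± 0.46), an endothelial gene as well, were the 4 largest with Dppa4 (3.49 ± 0.29, 62.9% unique 50-base windows), and Tdgf1, an exception named after its value was seen, was lower (-1.11 ± 0.26). Markers of undifferentiated cells stood at 12.5 ± 5.61 and 34.6 ± 8.46 CPM for Nanog and at 5.96 ± 3.5 and 20.3 ± 5.05 CPM for Sox2 in WT and iEtv2 SP. Most genes of glycolysis and hypoxia were higher, among them the vasoactive peptide gene Adm (3.48 ± 0.21), Pdk1 (3.12 ± 0.16) and Hk1 (1.79 ± 0.11). The 19 glycolysis and hypoxia genes tested held 13 higher, 1 lower and 5 not called. Glycolysis and hypoxia genes adjusted over the list alone gave 14 higher and 1 lower (camera adjusted p = 3.33e-06, and adjusted p = 0.235 with an estimated correlation). Of the 11 neuroectoderm genes tested, 5 were higher, 2 lower and 4 not called. Neuroectoderm genes adjusted over the list alone gave 6 higher and 2 lower (camera adjusted p = 0.232, not called). In the endoderm list, 2 genes were higher, 4 lower and 10 not called, 2 and 3 adjusted over the list alone, and the median (-0.16) and mean (-0.32) were below 0 while the test pointed higher (camera adjusted p = 0.985). For stress genes the median was 0.27 and the mean -0.13, with the test pointing higher (camera adjusted p = 0.231), 7 genes higher, 1 lower and 9 not called, 6 and 1 adjusted over the list alone.

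With 8274 genes called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), 4296 higher and 3978 lower and 3148 of at least 2-fold (2119 higher, 1029 lower), this was the widest of the 7 comparisons. Hprt, a purine salvage gene named after its values were seen, stood at 3.14 to 4.65 CPM in the 6 WT libraries and 83.3 to 96.4 CPM in the 3 iEtv2 libraries. The A2lox cassette lies at the Hprt locus, so this difference can come from the construct.

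Calls were then compared between contrasts that share no library. Genes called in the same direction with the Etv2 reporter in DP and in SP numbered 1259 higher and 1237 lower, 3.40 and 3.83 times the overlap of independent lists, with 44 in opposite directions and a Pearson correlation of 0.628 across genes, which are not independent replicates. For the SP gate, WT and Etv2-negative reporter cells shared 624 higher and 468 lower genes, 6.43 and 8.11 times the independent overlap, with 3 opposite, and WT and Etv2-positive cells shared 466 and 224, 4.52 and 3.06 times, with 34 opposite. Against induced Etv2 the reporter effect in SP shared 534 higher genes where independent lists would share 540.4 (Fisher's exact p = 0.748) and 458 lower genes against 520.3 (Fisher's exact p = 0.000643). With DESeq2 the lower genes numbered 451 against 469 (Fisher's exact p = 0.324). DESeq2 tested 16287 genes in both, against 15354 for edgeR, and the independent overlap depends on that number. Whether the shortfall holds with DESeq2 therefore stays open. In the edgeR calls 1659 genes were called in opposite directions, 915 higher with the reporter against 553.6 for independent lists and 744 lower against 507.9. Among genes changed at least 2-fold in both, 154 were higher and 137 lower in both, 4.65 and 4.01 times the independent overlap, and 174 were opposite. Of the 174, 36 were higher with the reporter against 19.69 for independent lists, and 138 lower against 57.5. The reporter effect in DP shared 678 higher and 514 lower genes with induced Etv2, against 670.6 and 645.7 for independent lists (Fisher's exact p = 0.713 and 2.13e-11). With DESeq2 these were 682 and 497 against 613.2 and 528.6 (Fisher's exact p = 0.000711 and 0.0957). Here DESeq2 tested 17875 genes in both, against 15354 for edgeR. The change in these results can therefore not be credited to the tool. In the edgeR calls of this pair 1956 genes were opposite, 1073 higher with the reporter against 687 and 883 lower against 630.3, with a Pearson correlation of -0.047 across genes. At 2-fold in both, 140 were higher and 136 lower in both, 2.4 and 3.25 times the independent overlap, and 330 were opposite. Of the 330, 155 were higher with the reporter against 34.66 for independent lists, and 175 lower against 70.44. Shared and opposite genes thus both exceeded independent lists at 2-fold. Endothelial members lay on the shared higher side, while cardiac, sarcomere and lateral plate members were spread around 0 with the reporter in SP and were mostly lower with induced Etv2.

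**Figure D3:**
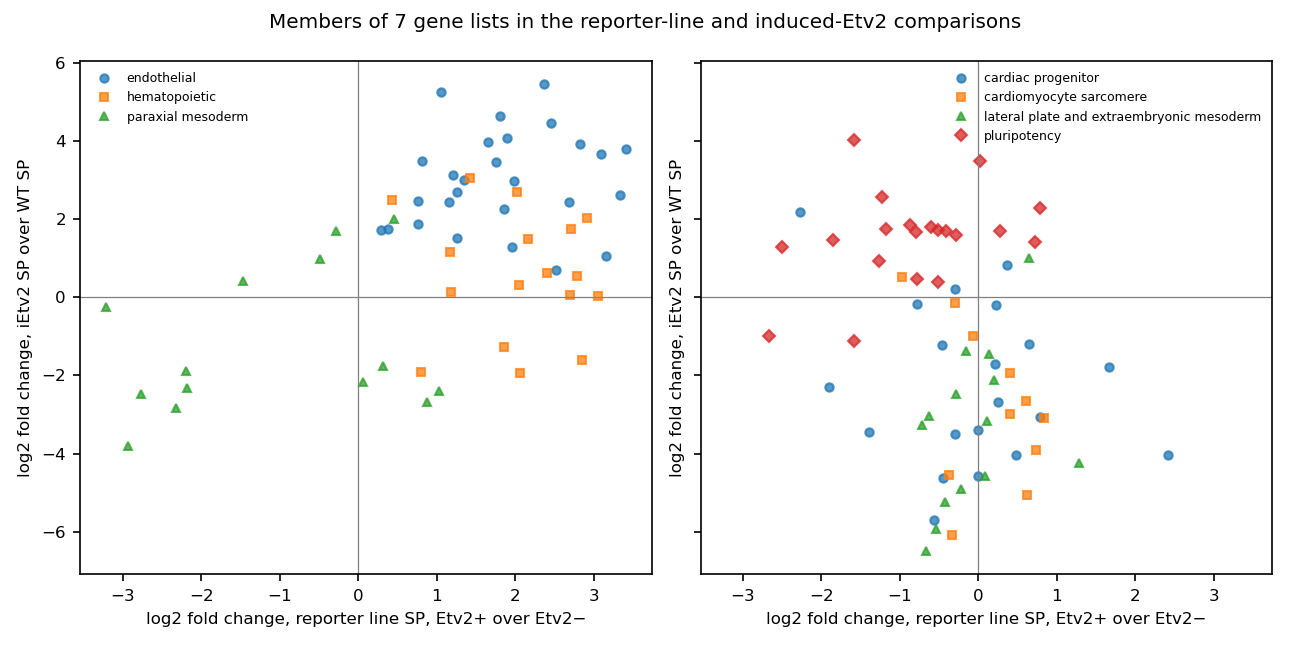
Log2 fold change of members of 7 gene lists with the Etv2 reporter in SP cells (horizontal axis) and in iEtv2 over WT SP cells (vertical axis), 1 point per gene tested in both. Endothelial genes lie mostly in the upper right, with medians of 1.81 in the reporter line and 3.07 with induced Etv2, and most sarcomere genes lie below 0 on the vertical axis with a median of -2.82.

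Of 154 tests of a list in a comparison, camera called 88 at its preset correlation, and 13 held with the correlation estimated from the data. These were the paraxial list in DP by reporter, in the gates of Etv2-negative cells and in the WT gates, the endothelial list in the gates of Etv2-positive and WT cells and with induced Etv2, the hematopoietic list in the gates of Etv2-positive and WT cells, the erythroid list in the WT gates, the cell cycle list in the gates of Etv2-negative cells, and the cardiac progenitor, sarcomere and lateral plate lists with induced Etv2. Calls not described above were all lost with it. In the direction of higher values these were, for the reporter, the BMP target and lateral plate lists in DP and the smooth muscle list in SP. The sarcomere, smooth muscle and BMP target lists were higher in the gates of Etv2-negative cells, and the endoderm list in those of Etv2-positive cells. Also higher were the erythroid and streak lists in the interaction, and the smooth muscle and lateral plate lists in the WT gates. Lower were the paraxial, streak, lateral plate and BMP target lists in the gates of Etv2-positive cells, and the smooth muscle and mesenchyme lists in the interaction. The glycolysis list in the WT gates was lower too, as were the paraxial, streak and mesenchyme lists with induced Etv2. With an estimated correlation the camera adjusted p was at least 0.144 for all of these higher and lower lists. The strand setting of the counts was not given in the sources used here, so values of genes that overlap an antisense gene, and of near-identical copies such as Bnip3 and Pgk1, are uncertain.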

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

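The test of opposite calls, the scaling, cell line and undifferentiated-cell tests of the induced genes and the other groupings of libraries were chosen after the results they bear on had been seen.

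A difference in the Etv2 reporter effect between the gates singled out 12 genes, by the interaction test of edgeR. The reporter effect was more positive in SP for Dysf (2.37), Adra2a (2.34), Inka1 (2.21), Wnt2b (2.16), Scube2 (1.87) and Hhex (1.73), as SP minus DP on the log2 scale. It was more negative in SP for Tdo2 (-2.77), Prrt4 (-2.65), Spin2c (-2.54), Ripor3 (-2.48), Extl1 (-2.43) and Gucy1b1 (-2.34).

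For the whole set of 702 interaction genes, Etv2-positive cells among the sorted negatives of a gate would shrink every effect of that gate in the same sense. Among the 1259 genes higher with the reporter in both gates, 66 had a smaller and 10 a larger effect in SP, so 13.2% went the less common way, which leaves such a mixture open for them. It cannot by itself give the 44 genes called in opposite directions, 25 higher in DP and lower in SP and 19 the reverse. Without the libraries of high ribosomal RNA share, the 702 differences kept their size, with a median ratio of 0.98 (quartiles 0.908 and 1.046). Their median standard error went from 0.17 to 0.18, and 119 genes were called. The 702 were called with those libraries in the fit, which favours genes on which the libraries of a group agree. A ratio near 1 was therefore likely beforehand and does not exclude a part of these libraries in the calls. A biological difference between the gates stays open and untested.

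Most cardiac progenitor, sarcomere and lateral plate genes were lower in iEtv2 SP than in WT SP, 37 of 46 tested. Reads shared with near-identical genes did not account for this: the 41 members with at least 90% unique windows had a median of -2.99 (quartiles -4.05 and -1.37) and 34 were lower. The other scalings and DESeq2 moved the median of all genes only from 0.002 to at most 0.01, too little to test scaling. But 1 factor per library moves all genes alike, and the median of the 46 members lay -3.02 from that of the other genes, with quartiles of -4.2 and -1.25 against -0.33 and 0.48, a gap such a factor cannot make. Cell line and doxycycline cannot be told apart from Etv2 induction, because they change with the group. Of 35 imprinted genes, a list chosen after Peg10 was seen, 15 were lower and 6 higher, where 50.8% of all genes tested were called.

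Most pluripotency genes were higher in iEtv2 SP than in WT SP, a list call lost with an estimated correlation (adjusted p = 0.346). The median of the 21 members lay 1.68 above that of the other genes, with quartiles of 1.3 and 1.8 against -0.33 and 0.47, a gap that 1 factor per library cannot make. Undifferentiated cells in the sort may contribute, since 4 of 4 markers (Nanog, Zfp42, Esrrb and Sox2) were higher. But these markers are list members, and the purity of the FLK1 sort was not given, so this stays open. Cell line or doxycycline also cannot be told apart from induction, because they change with the group. Hprt differed by 4.57 on the log2 scale, but the A2lox cassette lies at its locus, so the construct itself may account for that and it is no measure of other line differences.

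Other groupings of the same libraries were counted too. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and only 1, the real grouping, gave as many genes. Real counts and the highest of the other splits were 5435 and 0 for the reporter in DP, 4504 and 4 in SP, 1936 and 0 for the gates without and 2456 and 0 with the reporter, 2580 and 418 in WT, and 8274 and 0 for iEtv2. Every other split puts libraries of both real groups on each side, so the real difference enters the spread within groups. Low counts follow from that, and these splits do not bear on chance. For the interaction, 2 of 100 regroupings gave at least 702 genes, the real grouping included. Regrouping all 12 libraries mixes the gate and reporter effects into the spread within groups, and the median over the other regroupings was 0 genes, so this count, set aside after it was seen, does not bear on chance. The highest of the others gave 3033, with all 3 DP Etv2-negative libraries on the added side and all 3 SP Etv2-positive libraries on the subtracted side, and so follows the structure of the samples.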

How the results depend on the processing

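Leaving out both libraries of high ribosomal RNA share was chosen after the data were seen. Requiring a 2-fold change left 1276, 905, 494, 431, 269, 888 and 3148 genes for the reporter in DP and SP, the gates without and with it, the interaction, the WT gates and iEtv2. It left 463, 291, 276, 313 and 241 genes shared in direction between DP and SP, SP and iEtv2, DP and iEtv2, and the WT gates with the gates without and with the reporter. The interaction gave 1740 genes with no filter, 1237 with DESeq2, 1537 with a replicate block and 119 without both libraries of high ribosomal RNA share. Without those libraries, the reporter in SP gave 2459 and the gates with the reporter 1106, against 1324 with only the compared groups fitted; for the interaction that fit is the main one. Leaving out single libraries gave 4022 to 5062 genes for the reporter in DP, 3232 to 3608 in SP, 787 to 2268 for the gates without and 1342 to 2403 with the reporter, 50 to 1268 for the interaction, 1509 to 2683 in WT and 6834 to 8058 for iEtv2. Of 88 list calls, 13 held with an estimated correlation, 68 by fry, and all but the venous list of the reporter in DP (adjusted p = 0.0586) with the replicate block. The cause was not tested for counts that moved beyond what fewer libraries or a stricter call explain by construction. Of 8491 values of named genes under alternatives, 7664 stayed on their side of the threshold, 804 lost a call, 23 gained a call and 0 reversed. In the simulated data 52.2 to 73.1% of 1.5-fold changes between groups were recovered, so changes of that size were often missed there. Only 200 genes were changed in it, while 10.9 to 50.8% of genes were called between real groups. The adjusted threshold is stricter where fewer genes change, so these rates do not carry over directly to the real data.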

Other observations

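The Hox and imprinted genes below were chosen after their values were seen. Neither group was tested against other genes. Of the 9 Hoxb genes tested (chromosome 11, genes that pattern the body axis), 6 were higher, 1 lower and 2 not called with the Etv2 reporter in DP, among them Hoxb4 (1.51), Hoxb5 (2.98), Hoxb6 (2.28) and Hoxb7 (2.98), while Hoxb1 (-1.78) was lower. Of 20 Hox genes tested, 8 were higher and 2 lower there, and 4 and 2 in SP. In the WT gates 8 of 15 were higher and 1 lower. With induced Etv2 0 of 15 were higher and 11 lower, among them Hoxb1 (-5.6) and Hoxb2 (-4.18). Values are log2 fold changes from edgeR, and no Hox gene of these 4 comparisons lost its call under another scaling or with DESeq2.

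Imprinted genes are expressed from a single parental copy. With the reporter in DP, 15 of 34 tested were higher and 4 lower, while in SP 3 were higher and 6 lower. With induced Etv2, 6 of 35 were higher and 15 lower. Of all genes tested, 30.7, 25.5 and 50.8% were called in these comparisons. In iEtv2 SP, Peg10 (-2.29), Peg3 (-2.17), Zim1 (-2.44), Usp29 (-2.4) and Dlk1 (-2.52) were lower, and Plagl1 was higher (2.4). Of the 15 lower genes all 15, and of the 6 higher genes at least 4, kept their calls under each other scaling and DESeq2. In DP 15 of 15 higher and at least 3 of 4 lower did, and in SP at least 2 of 3 higher and 6 of 6 lower.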
